A study of Oryza sativa Japonica Group with 6 samples.

How the data were processed

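RNA from rice leaf blades of 2 groups of 3 samples, wild type and Line 13, was hybridised to one-colour rice oligonucleotide arrays. Per the labels' protocols, each biological replicate pooled at least 3 plants, 100 ng of total RNA was labelled with Cy3, and arrays were hybridised for 17 h at 65 °C. Per the file headers, spot intensity was measured with Agilent Feature Extraction 10.10.1.1, which subtracted background and detrended within each array, and the deposited processed intensity is on a linear scale and not scaled between arrays. The authors' deposited value table is also a linear intensity. Set against the scanner values, each of its columns equals the processed signal times 1 constant per array, from 1.61 to 7.66; how the constants were chosen is not given in the sources used here. Its column medians were 395.65, 426.55 and 412.25 for the wild-type arrays and 494.5, 554.8 and 561.45 for the Line 13 arrays, with no centring of genes. Its 75th percentiles were 2354, 2427 and 2381 for the wild-type arrays and 2494, 2514 and 2509 for the Line 13 arrays. As an alternative it therefore lies near the 75th percentile scaling of the fit.

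The log2 of the processed signal minus the 75th percentile of non-control spots of the array was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2 groups, no block), with Benjamini-Hochberg adjustment and a threshold of 0.05. Control spots and spots with outlier flags were left out, and repeated spots of a probe were averaged. Of 42477 non-control probes, 48 that the array design marks as no gene were left out. A probe was tested where it was well above background on all 3 arrays of at least 1 group, and a locus was represented by its probe with the highest mean. That gave 22139 loci and 93 probes without a locus. Of 6906 loci with several tested probes, 27 had probes called in opposite directions. A probe counted as well above background on an array where at least 50% of its spots were. Where a probe was so on no array of a group, the fold is a lower bound. The bound sets the mean of the bright group against a floored mean of the dim group. On each dim array this takes the higher of 2 signals, the probe's own and the lowest of any probe counted as well above background there. The lowest single spots well above background were brighter on average, so a floor taken from spots would give smaller bounds. The tables were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

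RAP locus identifiers came from the array files for 42004 probes, 28855 loci in all, and 1358 probes carried 2 different loci, of which the later name was used. The reference table of rice genes matched 0 of the loci, and the files used here carry no gene descriptions. The names and functions given for loci of the gene lists are therefore general knowledge of these loci, not checked against an annotation. Named genes were the linalool synthase locus, the largest rises and falls among non-overlapping called genes (at most 2 each way printed, as identifiers, since no description was at hand), and up to 4 members of each list with the smallest unadjusted p. PCNA and Os03g0645900 were chosen after their values were seen, as were the genes named in the closing section.

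Gene lists were tested with camera (preset correlation 0.01, and an estimated correlation) and fry, adjusted over 16 lists. Camera sets a list against the other genes, and fry asks whether the list itself differs, so with most genes called the 2 can part. A split of the genes into 4 equal sets by mean signal over the 6 arrays, and counts with genes at their bound, were chosen after the data were seen. Before the data were examined 7 of these lists were fixed as loci, and 15 keyword lists could not be built without descriptions. In their place 9 lists of loci were written once the files had been seen but before any fold change, so they are not the keyword lists planned, even where a name is shared. These 9 are photosynthesis, cell division, root-expressed genes, chlorophyll breakdown, heat shock proteins, phenylpropanoid pathway, other WRKY factors, tau glutathione S-transferases, and chitinases and glucanases. Later lists of a second set of proliferation genes, KNOX genes, floral organ MADS-box genes, anther genes and superoxide dismutases were written after the first results.

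The steps were tested on simulated data for Line 13 against wild type, with 3 and 3 arrays and 22232 genes. With 200 genes changed, 1% of 2-fold and 31% of 4-fold changes were called, and 2 unchanged genes were called. With 50% of genes changed 4-fold, a share nearer to that of the data, 91.4% of the changed genes were called and 3.22% of the calls were false. Noise was drawn independently for each gene and array. The simulated shares therefore do not cover correlated genes or a slide that goes with the group. Alternatives were another scaling (array median, quantile), the authors' value table, no filter or a filter on all 6 arrays, outlier flags kept, the mean of a locus's probes, every probe on its own, an intensity trend, the replicate number as a block, and each replicate left out. Normexp on median signals with an offset of 50 was chosen after seeing the data.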

Results

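Gene expression in rice leaf blades was measured on 6 one-colour oligonucleotide arrays, 3 labelled wild type and 3 labelled Line 13. Line 13 is a transgenic line made to overexpress a linalool synthase, the enzyme that turns geranyl diphosphate into the monoterpene alcohol linalool. Blades came from Nipponbare seedlings with 4 leaves grown at 25 °C, and each sample pooled at least 3 plants. The share of non-control spots well above background was 71.4%, 72.1% and 72.3% on wild-type replicates 1 to 3. On Line 13 replicates 1 to 3 it was 72.3%, 85.5% and 81.2%. The number of arrays limits the precision. Across genes, which are not independent replicates, the correlation of signals was 0.976 to 0.991 between wild-type arrays, 0.902 to 0.979 between Line 13 arrays and 0.604 to 0.740 between the 2 sets. Line 13 replicate 1 was the array that stood apart from the other two of its set.

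The linalool synthase locus Os02g0121700 was lower on the arrays labelled Line 13 than on those labelled wild type. Its log2 signal, relative to the 75th percentile of each array, was -3.32, -0.92 and -1.50 on the wild-type arrays and -6.52, -5.84 and -3.65 on the Line 13 arrays. The difference was -3.43 on the log2 scale (SE 0.90, n = 3 and 3), a 10.8-fold lower signal, with limma adjusted p = 0.0185. The exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 arrays can give. The locus had 1 probe, which was not well above background on Line 13 replicate 1. The value went against the label of an overexpressing line, so the groups are called the arrays labelled Line 13 and the arrays labelled wild type, and each direction below is a direction between labels. Whether the probe covers the introduced sequence is not given in the sources used here, and a probe outside it would check nothing. The adjusted p was 0.0613 without wild-type replicate 2, 0.0620 without wild-type replicate 3 and 0.0573 without Line 13 replicate 2, and a different background correction gave a difference of -1.61 with adjusted p = 0.0429.

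**Figure D1:**
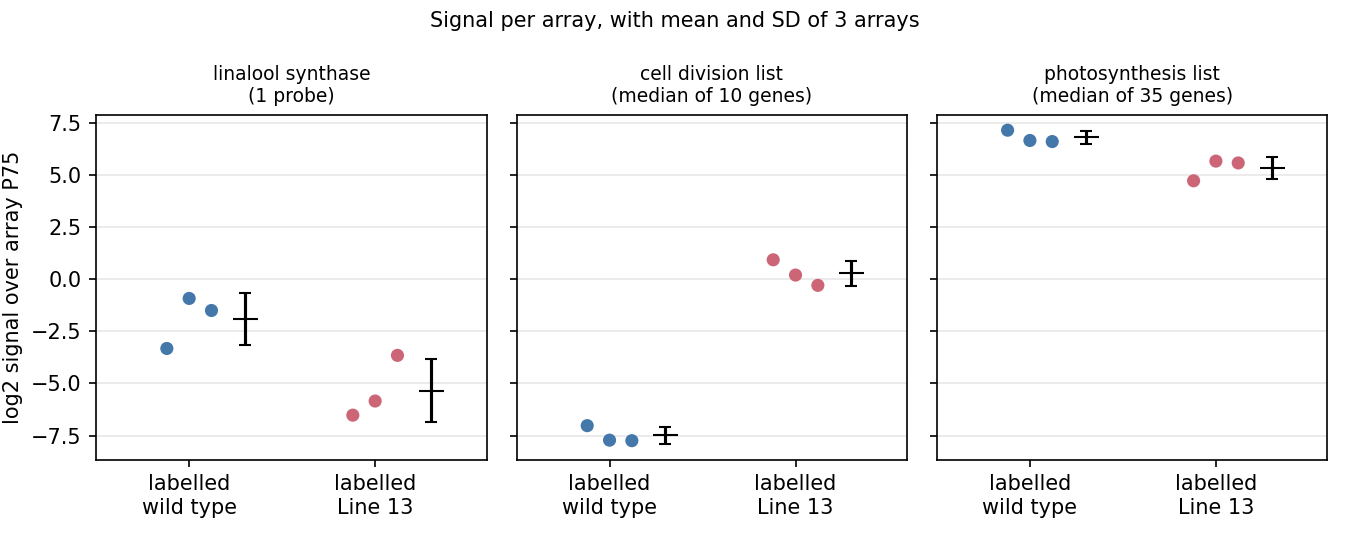
Each point is 1 array, the bar is the mean with the SD of 3 arrays, and the vertical axis is the log2 signal over the 75th percentile (P75) of the array, for the linalool synthase probe, the median of 10 cell division genes and the median of 35 photosynthesis genes. The linalool synthase probe lay between -6.52 and -3.65 on the arrays labelled Line 13, below the -3.32 to -0.92 of the arrays labelled wild type.

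The comparison of the arrays labelled Line 13 with those labelled wild type asks which leaf genes differ between the labels. Cell division genes were far higher, and photosynthesis, chlorophyll breakdown, circadian clock, WRKY and phytoalexin genes were lower in the median, on the arrays labelled Line 13. These 6 of 16 lists passed the set test camera at a preset correlation, 0 of them passed with an estimated one, and the counts of some moved with the processing. Of 22232 genes tested with limma, 5950 were higher and 6222 lower at adjusted p under 0.05, together 54.7% of the genes tested. Fitted changes of 2-fold or more were called for 5103 higher and 4612 lower genes, and of 32-fold or more for 973 higher and 54 lower genes. With genes below background at their bound, the counts at 32-fold were 785 and 47, and among genes well above background on all 6 arrays 118 and 12. For 68.5% of genes the sets did not overlap, with all 3 values of a set on the same side of the other set. Genes picked without regard to the sets would give 10% by chance. The filter picked probes by the sets, keeping those well above background on all 3 arrays of either set. The 10% therefore does not apply to these genes, and the 68.5% has no chance rate here to be set against. Of the called genes, 1681 were not well above background on any wild-type array, and 103 were not on any Line 13 array. Their folds are therefore bounds. On wild-type replicates 1 to 3 the lowest spot well above background had a processed signal of 11.7, 14.1 and 13.6. The 75th percentiles there were 720, 883 and 959. On Line 13 replicates 1 to 3 the lowest were 7.33, 6.62 and 7.97, with 75th percentiles of 325, 1559 and 932. The detection level thus differed between arrays, and its part in the gap between 1681 and 103 was not tested. The calls followed the signal level: the 5558 dimmest genes had 2247 higher and 1250 lower (median log2 difference 0.43), and the 5558 brightest 1020 higher and 1920 lower (median -0.25). Scaling each array to its median instead of its 75th percentile moved the median of all genes by -0.31 and gave 4685 higher and 8324 lower genes, 36.0% of the calls higher against 48.9%. All wild-type arrays shared 1 slide and scan date, and all Line 13 arrays shared another such pair. The layout therefore does not separate slide or scan from group. Slide and date were numbered together, so which of them differed is not told apart. The group difference had an SD of 0.0557 over the 7 spike-in probes well above background on all arrays, against 2.16 over genes. The closing section describes these probes. They bear on the reading of slides and scans only, for signals well above background. Without wild-type replicate 2 the number of lower genes was 4066.

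Among the largest rises of genes whose sets did not overlap were those of Os12g0114800, at least 9809-fold higher, and Os01g0251400, at least 5085-fold higher. Among the largest falls were those of Os01g0383700, at least 1992-fold lower, and Os05g0202800, 259.9-fold lower (-8.02 on the log2 scale, SE 0.32). The last was well above background on all 6 arrays, while each of the others was not on any array of its dim set, so that bounds and folds have no order between them. The sources used here do not pair these loci with gene names.

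Cell division genes rose together. All 10 tested members were higher on the arrays labelled Line 13, with a median log2 difference of 6.97, or 6.16 with members below background at their bound. The count was also 10 adjusted over the list alone. A B-type cyclin that drives entry into mitosis, Os06g0726800, was at least 168-fold higher, and the replicative helicase subunit MCM6, Os05g0235800, at least 84.5-fold higher. The plant-specific mitotic kinase CDKB2;1, Os08g0512600, was higher by 6.70 on the log2 scale (SE 0.37) and was well above background on 2 of 3 wild-type arrays. The sliding clamp of DNA replication, PCNA, Os02g0805200, rose by 2.81 on the log2 scale (SE 0.27). The set test camera with a preset correlation gave adjusted p = 6.41e-06 over 16 lists, and adjusted p = 0.722 with an estimated correlation, and the set test fry gave adjusted p = 0.000403. Only 3 of the 10 genes were well above background on all wild-type arrays, and with a filter on all 6 arrays these 3 rose with a median of 2.81. A background correction chosen after seeing the data gave a median of 3.33 with 9 of 10 higher, so the size of the rise depends on how dim signals are treated.

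Photosynthesis genes were mostly lower on the arrays labelled Line 13, where the cell division genes were higher. Of 35 tested, 22 fell and 2 rose (23 and 3 adjusted over the list alone), with a median log2 difference of -1.08. An outer antenna gene of photosystem I, Os02g0197600, fell by 2.08 on the log2 scale (SE 0.23), the photosystem I subunit gene Os12g0420400 fell by 2.09 (SE 0.32), and the Calvin cycle gene Os03g0267300 for fructose-1,6-bisphosphatase fell by 1.77 (SE 0.31). A light-harvesting gene of photosystem II, Os01g0720500, went the other way and was 98.4-fold higher, 6.62 on the log2 scale (SE 0.70). Camera gave adjusted p = 0.00292, and adjusted p = 0.798 with an estimated correlation, and fry did not pass, with adjusted p = 0.0982. All 35 genes were among the 5558 brightest, and their median was -0.82 relative to the median of those. Without wild-type replicate 1 the number that fell was 12, and without wild-type replicate 2 it was 14, and the number that rose ran from 1 to 3 when 1 array was left out. Under quantile normalization the median was -0.37, 8 members fell and 5 rose, and camera gave adjusted p = 0.705.

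All 6 tested genes of chlorophyll breakdown and senescence fell, also adjusted over the list alone, with a median log2 difference of -2.16. Pheophorbide a oxygenase, Os03g0146400, which opens the chlorophyll ring, was 3.99-fold lower (SE 0.20 on the log2 scale). The pheophytinase gene Os06g0354700, known as NYC3, fell by 2.55 (SE 0.24), and the stay-green gene Os09g0532000 fell by 2.32 (SE 0.56). Camera gave adjusted p = 0.00593, and adjusted p = 0.722 with an estimated correlation, and fry gave adjusted p = 0.00443. Without wild-type replicate 3 the number that fell was 4.

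Circadian clock genes were lower. Of 10 tested, 7 fell and none rose, the same counts as adjusted over the list alone, and the median gene was 2.14-fold lower. The morning transcription factor LHY, Os08g0157600, was 10.3-fold lower, with a log2 difference of -3.37 (SE 0.19). The pseudo-response regulators PRR73, Os03g0284100, and PRR37, Os07g0695100, were 2.81-fold and 2.14-fold lower (SE 0.25 and 0.20 on the log2 scale). Camera gave adjusted p = 0.00926, and adjusted p = 0.722 with an estimated correlation, and fry gave adjusted p = 0.000403. The time of harvest is not given in the sources used here.

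Genes of diterpenoid and flavonoid phytoalexin synthesis, the antimicrobial compounds of rice, were lower. Of 16 tested, 9 fell and none rose (11 fell adjusted over the list alone), with a median log2 difference of -2.20. The diterpene cyclase gene CPS4, Os04g0178300, fell by 2.95 on the log2 scale (SE 0.52), the cytochrome P450 gene CYP76M7, Os02g0569900, fell by 3.56 (SE 0.77), and the momilactone A synthase gene Os04g0179200 fell by 2.58 (SE 0.61). Camera gave adjusted p = 0.00593, and adjusted p = 0.722 with an estimated correlation, and fry gave adjusted p = 0.0473. With only probes well above background on all 6 arrays, 4 of 8 fell, the median was -1.79 and camera gave adjusted p = 0.116, within a range of 0.000123 to 0.116 over all alternatives. With the other background correction 4 of 16 fell and the median was -0.82, and with array medians as the scale 14 fell. Without wild-type replicate 2 the number that fell was 6, and without Line 13 replicate 1 it was 10, with 1 higher.

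WRKY transcription factor genes outside the pathogenesis list were lower. Of 18 tested, 11 fell and none rose, the same counts as adjusted over the list alone, with a median log2 difference of -1.65. Os08g0386200 fell by 3.37 on the log2 scale (SE 0.54) and Os07g0680400 fell by 3.25 (SE 0.45). Camera gave adjusted p = 0.00548, and adjusted p = 0.722 with an estimated correlation, and fry gave adjusted p = 0.0192. With the other background correction 8 fell and the median was -1.05. Among salicylate-linked and pathogenesis-related genes, 11 of 20 fell and 3 rose, again the same counts adjusted over the list alone, and camera did not pass, with adjusted p = 0.0867, or 0.798 with an estimated correlation, and neither did fry, with adjusted p = 0.109. The number that fell was 6 without wild-type replicate 1, wild-type replicate 2 or Line 13 replicate 2. The salicylate receptor gene NPR1, Os01g0194300, fell by 1.74 on the log2 scale (SE 0.21) and WRKY45, Os05g0322900, a regulator of salicylate-induced resistance, fell by 2.27 (SE 0.39). A gene of the PR4 family, Os11g0592200, rose by 3.53 (SE 0.64). At the preset correlation, camera for this list had adjusted p = 0.0373 without wild-type replicate 3 and 0.0269 without Line 13 replicate 3, within a range of 0.00580 to 0.304 over all alternatives.

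The plastid isoprenoid pathway, which makes the precursors of monoterpenes such as linalool, had 7 of 13 tested genes lower and 2 higher, the same counts adjusted over the list alone. Its median log2 difference was -1.35. The genes of its last enzymes were lower: HDS, Os02g0603800, fell by 2.47 on the log2 scale (SE 0.16) and HDR, Os03g0731900, fell by 2.46 (SE 0.19). DXR, Os01g0106900, which makes the first committed intermediate, fell by 2.23 (SE 0.26). Camera did not pass, with adjusted p = 0.132, while fry did, with adjusted p = 0.00411. None rose with array medians as the scale, where 8 fell, or without wild-type replicate 2 or Line 13 replicate 2. Carotenoid and abscisic acid genes, which draw on the same precursors, had 7 of 11 lower and 2 higher (8 and 2 adjusted over the list alone), with a median of -1.55 and camera adjusted p = 0.0603, or 0.722 with an estimated correlation, where fry gave adjusted p = 0.00988. Phytoene synthase 2, Os12g0626400, fell by 1.97 (SE 0.25). The 9-cis-epoxycarotenoid dioxygenase genes, of the step that commits to abscisic acid, went both ways. Os12g0617400 fell by 2.77 (SE 0.24), Os07g0154100 was at least 5.44-fold higher and Os03g0645900 rose by 1.46 (SE 0.46). Without any 1 wild-type array the number that rose was 1. At the preset correlation this camera result passed without wild-type replicate 1, with adjusted p = 0.0480, within a range of 0.000193 to 0.201 over all alternatives.

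Jasmonate genes went both ways. Of 26 tested, 9 fell and 3 rose, the same counts adjusted over the list alone, with a median log2 difference of -0.38, camera adjusted p = 0.168 and fry adjusted p = 0.109. With array medians as the scale 14 fell and the median was -0.69, and without Line 13 replicate 1 the number that rose was 5. The lipoxygenase gene Os08g0508800 fell by 3.80 on the log2 scale (SE 0.57), and another, Os12g0559200, fell by 3.05 (SE 0.38). Of the allene oxide synthase genes, Os03g0225900 fell by 1.97 (SE 0.35) and Os03g0767000 rose by 0.96 (SE 0.18). Gibberellin genes had 3 higher and 2 lower of 11, also adjusted over the list alone, and 1 higher without wild-type replicate 2 or Line 13 replicate 2. The gibberellin 20-oxidase gene SD1, Os01g0883800, fell by 1.58 (SE 0.28) and the ent-copalyl diphosphate synthase gene CPS1, Os02g0278700, well above background on 2 of 3 wild-type arrays, rose by 1.85 (SE 0.36). The gibberellin median was -0.16 where the mean was 0.07 and camera pointed up, with adjusted p = 0.990, and fry down, with adjusted p = 0.732.

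Genes of root tissue split. Of 6 tested, 2 rose and 2 fell, also adjusted over the list alone, with a median of -0.66, a mean of 1.52 and a camera direction up (adjusted p = 0.990, and 0.000403 with fry). The root cortex gene RCc2, Os02g0662100, was at least 2971-fold higher and the nicotianamine synthase gene Os03g0307200, of iron uptake and transport, fell by 3.62 on the log2 scale (SE 0.75) and was well above background on 1 of 3 Line 13 arrays. The counts were 1 and 1 without wild-type replicate 2 or 3, and 3 higher of 7 without Line 13 replicate 1. Heat shock protein genes had 2 of 12 higher and none lower, and 0 of either adjusted over the list alone (camera adjusted p = 0.352, fry 0.0580). The small heat shock gene Os01g0136200 rose by 1.75 on the log2 scale (SE 0.56), and no gene of the list was called without any 1 wild-type array or without Line 13 replicate 2, while 3 rose without Line 13 replicate 1. Phenylpropanoid genes had 2 of 13 higher and 2 lower, and 2 higher and 0 lower adjusted over the list alone. The phenylalanine ammonia-lyase genes Os02g0626100 and Os04g0518100 rose by 2.77 (SE 0.31) and by 2.47 (SE 0.25), and another, Os04g0518400, fell by 1.49 (SE 0.47). Without Line 13 replicate 1 the list had 4 higher and 3 lower, and none lower without wild-type replicate 1, wild-type replicate 2 or Line 13 replicate 2. The phenylpropanoid median was 0.13, or -0.19 with array medians as the scale (camera adjusted p = 0.913 and fry 0.406). Tau-class glutathione S-transferase genes had 2 of 13 higher and 4 lower, and chitinase and glucanase genes 2 of 10 higher and 2 lower, the same counts adjusted over each list alone. Without wild-type replicate 1 or 2, 1 of the tau-class genes rose and 2 fell, and without Line 13 replicate 1, 5 of 14 rose and 5 fell, with a median of 0.18. Without Line 13 replicate 3, 6 of the tau-class genes and 3 of the chitinase and glucanase genes fell. Their medians were -0.27 and -0.22 (camera adjusted p = 0.688 and 0.836, fry 0.732 and 0.876), and the chitinase and glucanase mean was 0.04.

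**Figure D2:**
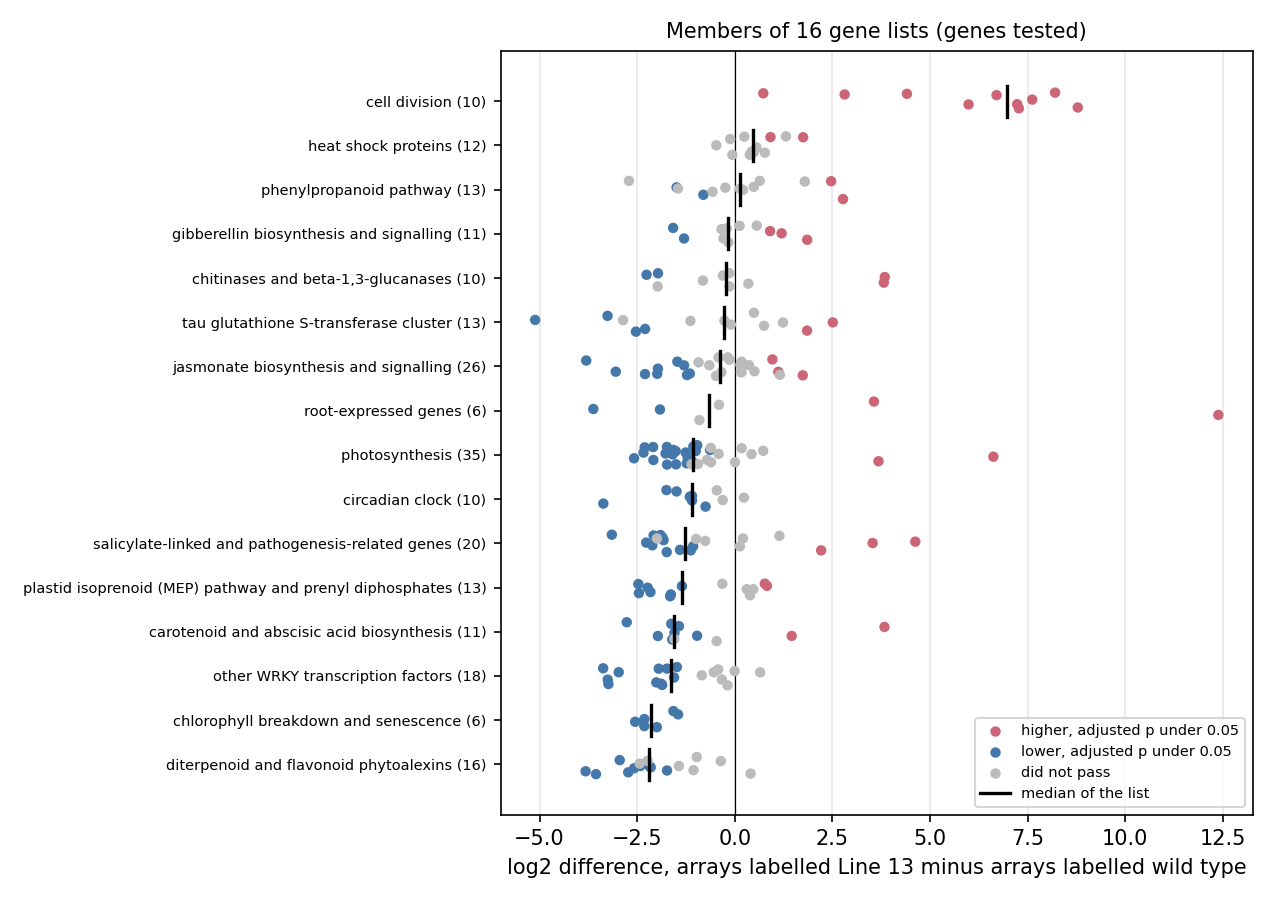
Each point is 1 gene, placed by its log2 difference between the arrays labelled Line 13 and those labelled wild type, for 16 gene lists with the number of genes tested, and the bar is the median of the list. Cell division is the list farthest to the right, with a median of 6.97, and the phytoalexin list the farthest to the left, with a median of -2.20.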

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

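Normexp was the alternative chosen only after the data were seen. Planned normexp on mean signals was not run, since no mean signal was at hand. A slide or scan block was not run, since each pair of slide and scan date holds 1 group. The 15 keyword lists were not built. Of 1839 alternative values of 111 named genes and probes, 1760 kept their direction and side of the threshold. Most of these genes were picked by p or size in the same fit, so this share says little about other genes. Os03g0645900 was not among the 111. Dim signal limits the folds of genes not well above background. The replicate number as a block gave 10900 called genes against 12172. Deviations of same-numbered arrays correlated at 0.11, -0.02 and -0.00, so no strong effect shared by replicate number was seen. The sources used here name no pairing, and these values cannot settle it.

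With a filter on all 6 arrays, 3794 genes were higher, 2910 of them by a fitted 2-fold or more, the linalool synthase probe was not measured, the phytoalexin median was -1.79 (camera no longer passed) and the carotenoid median -1.55 (now passed); fewer genes were tested. With every probe on its own, 9354 were lower, 6943 by a fitted 2-fold or more, the jasmonate (-0.45), salicylate (-1.36) and carotenoid (-1.55) lists passed at the preset correlation, and the tau transferase and chitinase medians were 0.75 and 0.16; more probes were tested. The carotenoid list also passed with the replicate block (-1.55) and normexp (-1.34). Quantile normalization ended the photosynthesis call (-0.37). The phenylpropanoid median was -0.19 with array median scaling and -0.058 with no filter. Os01g0883100 was 0.036 in the value table. For these last settings the cause was not tested.

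Leaving out 1 array gave 4066 (without wild-type replicate 2) to 7509 lower genes and a linalool synthase difference of -4.27 to -2.84. List medians ran from -1.45 to -1.07 for salicylate, -0.21 to 0.19 for gibberellin, -1.82 to -1.13 for carotenoid, -0.94 to 0.0011 for root, -0.39 to 0.53 for phenylpropanoid, -0.69 to 0.18 for tau transferases and -0.93 to 0.44 for chitinase and glucanase genes. The WRKY gene Os05g0583000 ran from -3.14 to 0.58, because its other probe was the brighter without a wild-type array, and Os01g0883100 from -1.05 to 0.48. The cell division, senescence, clock and other WRKY lists kept direction and call in all 17 alternatives at the preset correlation, as far as the camera test goes. With an estimated correlation no list passed under any of the 16 alternatives where it was run (lowest adjusted p = 0.484), nor in the fit reported, where it was 0.722 for these 4 and for carotenoid, and 0.798 for photosynthesis, jasmonate and salicylate. The replicate block gave 14 photosynthesis genes lower and 1 higher.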

Other observations

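Probes of the microRNA miR398a, which represses copper/zinc superoxide dismutases, were well above background on all arrays labelled wild type and not well above background on any array labelled Line 13. The 2 probes of its precursor arms were at least 131-fold and 124-fold lower. The probe named for the mature sequence was lower by at least 6.23 on the log2 scale. The probe named for mature miR398b fell by 1.44 on the log2 scale (SE 0.32). Whether these probes read the mature microRNA or a longer transcript of its gene was not tested. Of 4 superoxide dismutase genes, 3 rose, among them Os08g0561700, 2.59 on the log2 scale (SE 0.37), and Os07g0665200, 2.12 (SE 0.26). The fourth, Os03g0219200, fell by 1.59 (SE 0.28). Release of these genes from the microRNA was put as a hypothesis before the 4 genes were looked at, and 3 of 4 higher is consistent with it. With 26.8% of all genes higher and only 4 genes in the list, it is weak evidence. Of 92 microRNA probes tested, 31 fell and 9 rose.

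The tests of scaling, labels and probe position below, and those of slide reading and scaling for the gene counts, were chosen only after the results were seen. The linalool synthase probe was lower on the arrays labelled Line 13, where an overexpressed gene would be higher. The scaling and background correction alternatives argue against those steps as the whole cause. The smallest fall over them was -1.61, more than 2 SE below 0. The filters do not bear on this. With no filter, or with outlier flags kept, the difference stayed at -3.43, as these settings do not alter this probe's signals. The filter that asks for a signal well above background on every array left the probe out. An exchange of the labels between the 2 groups stays open: the probe reached at most the 64.6th percentile on the arrays labelled wild type, neither the level set for an overexpressed gene nor below the median on all 3. A probe that lies outside the transgene also stays open, with 1 probe for the locus. The exchange and the probe position cannot be told apart here, and loss of expression in the line was not tested.

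About 54.7% of genes, and the cell division list with them, differed between the sets. Spike-in probes argue against hybridization, slide or scan reading as the whole cause, for signals well above background. Over the 7 of 10 spike-in probes well above background on all arrays, the SD of the group difference was 0.0557. That was 0.0257 of the SD over genes, 2.16. These SDs are not alike: each spike-in value averaged 32 spots, most gene probes had 1 spot, and the genes included dim ones. The mean difference of the 7 was -0.63, with array means from -1.90 on Line 13 replicate 2 to 0.89 on Line 13 replicate 1. Their SD does not rule out such a common shift. The spike-in probes left out as dim differed by -1.30, -0.72 and -1.11. These probes share one kind of sequence and do not cover harvest or RNA extraction, which stay open along with the genotype. At least 42.0% of genes were called under each scaling or background alternative tried, which argues against the choice among these as the whole cause. None of them scaled the arrays to the spike-in probes, so a wrong common level of an array was not tested. Of the 10 splits of the 6 arrays, 1, the real one, gave 12172 genes and the highest of the others 0. The 10 splits are too few for a share under 0.05. Each other split puts arrays of both labels on each side, so the difference between the sets widens the spread within sides. The 0 therefore says nothing on what made the sets differ.

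Cell division genes were higher on the arrays labelled Line 13. Tissue with dividing cells stays open: all 6 genes of a second proliferation list rose (median 6.04, or 5.73 with bounds), but that list was written after the first was seen and repeats the same observation. Shoot apex or stem in the sample stays open: of 5 KNOX genes 3 were tested, and 2 were higher where 3 were asked for. Of 14 KNOX probes, 10, 14 and 4 were well above background on Line 13 replicates 1 to 3, and 2 on each wild-type array. These probe counts also depend on the detection level of each array, which differed. The cell division median was 0.94, 0.20 and -0.29 on Line 13 replicates 1 to 3. Flowers or young panicle stays open by the bounds set beforehand, as 5 of 10 floral MADS-box genes were tested, of which 0 rose and 2 fell, but 4 were well above background on all arrays labelled Line 13. As many, 4, were so on all arrays labelled wild type. None of the 5 differences was positive in the fit reported, so these genes give no support for this source. That of Os01g0883100 was near 0, at -0.033, and ran from -1.05 to 0.48 when 1 array was left out. Of 2 anther genes tested, 1 rose, and the labels give leaf blade as the tissue for all samples.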
